A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

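The deposited files are peak lists, 1 per library and not pooled, for 16 Break-seq, 2 Orc5 ChIP-seq and 4 Arp5 ChIP-seq libraries. The 8 NET-seq libraries of the 30 samples have no list here and are not analysed here. Per the labels' protocols, cells grew to log phase, and Break-seq cells had 3 h of rapamycin. The ChIP-seq protocol names nocodazole for 1 h, rapamycin at 8 µg/ml for 1 h and arrest in G1 with alpha factor at 5 µg/ml for 1 h. It speaks of depletion of Orc2 for all ChIP-seq samples, whereas the genotypes are Orc5 and Arp5, so the depleted protein is named here by the genotype. Reads were 75 bp for Break-seq and 50 bp for ChIP-seq, per the labels. The submitters' processing notes name Bowtie2 and the build sacCer3, without versions; the peak callers and their settings are not given in the sources used here.

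Each deposited Break-seq peak carries a score, a fold over the local background, and −log10 of a p-value and a q-value, as the narrowPeak layout has it. Per the file headers, each deposited Arp5 peak has a count of ChIP reads, a scaled control value, a ratio of both (enrichment), and a q-value. Where Arp5 peaks were ranked by score, the column after the enrichment was used, lowest values first. The deposited Orc5 lists hold positions only. These values are the authors' and were used only to describe, rank or filter peaks within a list. A fold describes a peak's height in one library and was not tested between groups.

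Peak lists give no read totals, so depth per library is unknown. As a proxy, the pileup and the background of each Break-seq peak were recovered from the authors' fold and −log10 p under a Poisson model, with whole pileups accepted within 0.001 of −log10 p. A whole pileup was found for 100% of the peaks of each list, and the lowest background of a list was taken. The precision of a share follows from the number of peaks: 95% Wilson intervals were computed for shares of break peaks and exact binomial ones for Orc5 sites. Peaks are not independent molecules, so intervals cover counting error only.

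Samples were grouped by genotype and treatment as the labels give them. Groups, tests, feature classes, gene lists and most alternatives were chosen before the data were examined. Nothing in the labels says that replicates came from separate cultures, so p-values of tests between libraries measure a spread that may be technical. Position permutation p-values come from random places for the peaks of 1 list or the regions of 1 set. They hold no spread between libraries. The plan was to use annotated replication origins, but the gene table used here (6477 genes, assembly R64, the same as sacCer3) has none. Orc5 peaks without rapamycin of up to 10 kb were used as origins instead, 1412 sites with 500 bp on each side, which together cover 17.0% of the genome. Whether each site is an origin was not checked. Of the sites 1172 were under 1 kb wide and 226 lay at tRNA genes, so many may not be origins. Early and late origins by name, centromeres and annotated long terminal repeats were not analysed. The class of Ty-length frames (40 reading frames without a gene name, 5200 to 5450 bp long) was set after the data were seen. Strand was read from the systematic gene names.

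For each library the percentage of peaks overlapping a class by at least 1 bp was computed. Effects of HU, INO80 depletion and Mot1 depletion were tested with exact two-sided permutation tests over 1296 arrangements, with labels permuted within strata of the other factors. The smallest p these can give is 0.00154. Benjamini-Hochberg adjustment ran over 24 such tests. Positions were tested within lists against 1000 random placements on the same chromosome (a permutation of peak positions, two-sided), with 448 tests for Break-seq (384 outside repeats, where peaks and placements that touch a repeat were left out), 112 for Arp5 and 50 for Orc5. Similarity between lists was the Jaccard index in base pairs, with 100000 permutations. Regions were merged unions of all peaks of an assay, and a region counted as gained with peaks in every library of one group and in none of the other. Up to 10 gained and 10 lost regions per comparison qualified for naming, first those in a feature class or gene list, then by summed width, as did up to 4 genes per list by the number of libraries with a peak. TRP1 and HHF1 were named after their values were seen, as genes beside known origins. Arp5 lists were compared on the 11 chromosomes with peaks in all 4 lists and without peaks over 10 kb, a limit set after the lists were seen.

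The procedures were tested on simulated data. With lists simulated for the first INO80 library (310 nuclear peaks), 4 of 100 tests on random lists passed the threshold of 0.05, and all 20 lists with 25% of peaks planted in a class were recovered. Outside repeats (36 peaks) 1 of 80 tests on random lists passed, and 18 of 20 lists with peaks planted at promoters were recovered. Random peaks were placed independently of each other, so these runs cannot show how the placement test behaves when peaks lie close together. The stratified test called 14 of 200 simulated experiments without an effect and all 200 with a shift of 4 SD. Pileups were recovered for 500 of 500 simulated peaks, and the similarity test called 4 of 50 sets without and 50 of 50 with shared groups. Alternatives changed the origin window, the peak filter, the overlap rule, the measure, the random model, the replicate block and the libraries used. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.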

Results

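The series holds peak lists from budding yeast (Saccharomyces cerevisiae) strains made for anchor-away, in which a protein tagged with FRB is pulled out of the nucleus when rapamycin is added. Break-seq, which labels and sequences broken DNA ends, was run on 16 libraries, with 2 in each of 8 groups. The strains were one labelled WT-FRB (WT here) and strains depleted of INO80, a chromatin remodelling ATPase, of Mot1, which removes the TATA-binding protein from DNA, or of both. Each strain was sampled with and without 100 mM hydroxyurea (HU), which lowers deoxynucleotide pools and stalls replication forks, after 3 h of rapamycin. ChIP-seq peak lists covered Orc5, a subunit of the origin recognition complex (1 library with and 1 without rapamycin), and Arp5, an INO80 complex subunit (2 and 2). The 8 NET-seq libraries are not analysed here.

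The break lists differed widely in length. The WT libraries held 510 and 373 peaks and those with HU 352 and 318. The INO80 lists held 365 and 318 peaks, or 358 and 347 with HU. The lists depleted of both proteins held 310 and 310 peaks, or 222 and 180 with HU. The Mot1 lists held 40 and 14 peaks, and 24 and 5 with HU. Across strains the number of peaks differed by -0.519 log2 units with HU (exact permutation within strain, p = 0.134, adjusted p = 0.248), and this call changed in some of the alternatives given below. Read totals per library are unknown, so the lowest local background recovered from the peaks served as a rough measure of depth. It was 31.1 and 24.2 reads in the WT lists, 11.0 and 10.7 in WT with HU, and between 6.66 and 21.2 in the 8 lists with INO80 depleted. In the Mot1 lists it lay between 0.167 and 1.13 and rested on 1 peak per list.

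Break peaks of the 12 lists other than Mot1 lay mainly in repeated DNA. A class chosen after the data were seen held reading frames as long as the long frame of Ty1 and Ty2, retrotransposons of yeast. They are called Ty frames here by length and lack of a gene name alone, since no Ty annotation was used. These frames covered 1.75% of the genome but carried 49.9% ± 8.69 (SD, n = 12) of nuclear break peaks. That was 14.6 to 29.0 times the number expected from random placement. Of the 40 frames, 34 had a break peak in all 12 lists. The last 10 kb of chromosomes were enriched 8.10 to 13.2 times, and the subtelomeric gene families 8.93 to 14.0 times. The YRF1 genes, which encode helicases in the Y' elements of chromosome ends, stood out in that family: YRF1-1, YRF1-2, YRF1-3 and YRF1-5 each had a peak in all 12 lists. All 12 lists passed the placement test, a permutation of peak positions, for these 3 classes (adjusted p = 0.00689, the smallest reached). The ribosomal RNA genes passed in 6 of the 12 lists, but in far fewer under each of the 3 alternatives given below. Ty frames, ribosomal DNA, chromosome ends and mitochondrial DNA together took 81.5% ± 9.93 (SD, n = 12) of all peaks.

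Promoters, the 500 bp upstream of protein-coding genes, held 12.3% ± 7.48 (SD, n = 12) of nuclear peaks in the 12 lists, against 35.6% expected by placement over whole chromosomes. That shortfall was not seen away from the repeats. With only the 22 to 202 peaks per list outside Ty frames, ribosomal DNA, chromosome ends and mitochondrial DNA, placed at random outside them (a test added after the data were seen), promoters held 32.5% ± 12.6 (SD, n = 12) of peaks against 33.8% expected, and the number of depleted lists went from 11 to 0. The first WT library was enriched there, with 137 of 202 peaks at promoters (2.23 times, position permutation, adjusted p = 0.0256 over 384 tests). Intergenic regions between divergent genes were likewise depleted in 11 lists with all peaks and in 0 outside repeats, and were enriched in that WT library both ways. At tRNA genes no list passed with all peaks, with 2 to 11 peaks per list, and 5 of the 12 lists were enriched outside repeats. Among the gene lists, none of the members of the DNA damage and ribonucleotide reductase, INO80 complex, phosphate and inositol, Mot1 and TFIID, replication initiation, heat shock and other highly transcribed lists had a break peak in any of the 16 lists. Ribosomal protein genes were represented by RPL4B and RPS6A, histone genes by HTB1 and glycolysis by PGK1 and ADH1, each in 1 library. The flocculins, cell wall adhesins with internal repeats, passed the enrichment test in 2 lists, with FLO1 (I:203403-208016) having a break peak in 11 of the 16 lists and FLO5 and FLO9 in 4 each. The hexose transporter HXT7 had a peak in 5 lists and its neighbour HXT6 in 3, and that list passed no enrichment test.

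Break maps were on average more alike within groups than between them. Libraries of one group shared a mean Jaccard index of 0.489 and libraries of different groups 0.259 (one-sided permutation p = 0.00014, 100000 resamples). Within the 12 lists other than Mot1 the means were 0.529 and 0.440 (one-sided permutation p = 8e-05). Not every group stood apart. The index within WT with HU was 0.422 and within the strain depleted of both with HU 0.434, below that mean between groups. Within WT without HU it was 0.453. Outside Mot1, its second library shared more than that with most lists of other groups, such as the INO80 lists without HU (0.554 and 0.571). The exceptions were the first WT library with HU (0.366) and both HU lists depleted of both. The first WT library without HU shared at most 0.444 with a list of another group. In the Mot1 strain the index was 0.379 within the group without HU, 0.364 with HU and 0.265 to 0.551 between them. The peaks merged into 759 regions, of which 86 were present in all 12 lists, 2 in all 16 and 345 in 1 library only.

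The first comparison asked whether HU moved breaks toward replication origins, taken as Orc5 peaks without rapamycin and 500 bp on each side. In WT cells 26 regions had a peak in both HU libraries and in neither library without HU, and 18 of them (69.2%) lay at Orc5 sites, against 5.93 expected by random placement (position permutation p = 0.002, the smallest the 1000 placements can give, adjusted p = 0.0120 over 18 tests). They included regions at NCE103, encoding carbonic anhydrase (XIV:560396-562117, fold over background 3.47 ± 0.111, SD, n = 2), TRX1, encoding a thioredoxin (XII:230972-232246, 2.22 ± 0.174), LSO2 (VII:835958-836659, 2.73 ± 0.0125), SGN1 (IX:355608-356243, 2.87 ± 0.884), and BUL1 with RCE1 (XIII:814923-816089, 2.43 ± 0.112). Another lay next to a tRNA gene on chromosome XII (373034-374294). The p for the 26 regions concerns position only and holds no spread between libraries. Placement over whole chromosomes may expect too few, since outside repeats 36.8% ± 11.2 (SD, n = 12) of break peaks lay at Orc5 sites against 21.5% expected. The lowest background also differed, with 31.1 and 24.2 in WT without and 11.0 and 10.7 with HU. A gained region therefore cannot be credited to HU. The 45 regions broken in WT without HU and not with it included 14 at Orc5 sites (31.1%, position permutation, adjusted p = 0.536), among them FDH1 and URA3, and 14 at chromosome ends, such as stretches at YRF1-4 and YRF1-5. YRF1-5 itself had a peak in all 12 lists other than Mot1, those with HU included, so such a region is not a whole gene. In the strain depleted of INO80, 18 regions were gained with HU, of which 10 lay in Ty frames and 3 at Orc5 sites (position permutation, adjusted p = 1). NCE103, SGN1 and HXT7 were among the 18 regions. Without HU 38 of the 40 Ty frames already had a peak in both INO80 libraries, so the Ty regions count stretches and not newly broken frames. No region was gained with HU in the strain depleted of both proteins, where 40 regions dropped out, and none in the Mot1 strain. The test of Orc5 overlap was chosen after the counts of regions were seen, and it was lost when only the higher-scoring peaks of each list, above its median score, were used (42.9% of the 7 regions then gained in WT, position permutation p = 0.613).

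The share of all break peaks at Orc5 sites passed no test for HU. It was 16.9% ± 6.06 (SD, n = 2) in WT and 20.2% ± 8.05 with HU, 9.70% ± 2.16 and 13.5% ± 0.498 in the INO80 strain, 48.6% ± 12.1 and 45.0% ± 7.07 in the Mot1 strain, and 11.8% ± 3.42 and 9.50% ± 0.701 in the strain depleted of both. Across strains the difference was 0.301 percentage points (exact two-sided permutation within strain, p = 0.904, n = 8 against 8, higher with HU in 2 of 4 strains). It was 6.83 points outside Ty frames, ribosomal DNA, mitochondrial DNA and chromosome ends (exact permutation p = 0.102), 3.62 points at Orc5 sites of at least 1 kb (exact permutation p = 0.0849) and -1.19 points by peak midpoints. Within lists, Orc5 sites were enriched for breaks in the first WT library without and the first with HU (1.23 and 1.33 times), depleted in 8 of the 12 lists other than Mot1, and neither in 2. The other WT library without HU was among the depleted ones (0.680 times). The depleted lists fell to 3 under a circular shift and to 2 with higher-scoring peaks, and the enriched ones to 0 in both. Outside repeats 0 lists were depleted and 5 enriched (position permutation, adjusted p = 0.0256 to 0.0438), namely the first WT library (2.18 times), both WT libraries with HU (2.91 and 2.54), the first INO80 library with HU (1.91) and the second depleted of both (1.79). Peaks at tRNA genes, where 226 of the 1412 Orc5 sites lay, were not left out. They made up 11.2% ± 4.32 (SD, n = 12) of peaks outside repeats, against 2.14% expected. The excess at Orc5 sites outside repeats therefore cannot be told apart from one at tRNA genes.

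**Figure D1:**
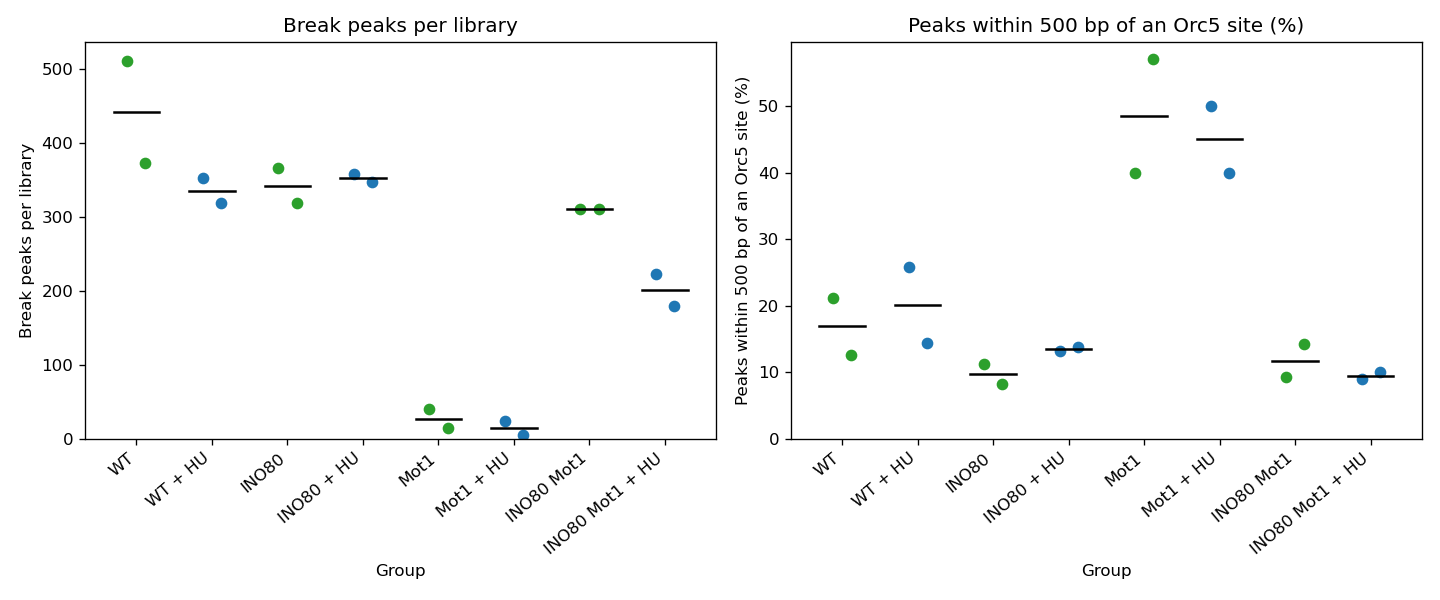
Number of break peaks per library (left) and percentage of each library's peaks within 500 bp of an Orc5 site (right) in the 8 groups. Each point is 1 library, green without and blue with HU, and the black line is the mean of the 2; the Mot1 lists hold 40 peaks or fewer and have the highest percentages.

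The second comparison addressed depletion of INO80. With HU, 14 regions were broken in both WT libraries and in neither INO80 library, and 12 of them (85.7%) lay at Orc5 sites, against 3.34 expected (position permutation p = 0.002, adjusted p = 0.0120). TRX1 and BUL1 with RCE1, gained with HU in WT, were in this set. So were regions at PAU7 (I:175948-176584, fold over background in WT 2.59 ± 0.501, SD, n = 2), DCV1 with the tRNA gene SUP11 (VI:167520-168295, 2.69 ± 0.327), CRF1 (IV:913455-913983, 2.45 ± 0.310), PES4 (VI:199522-199983, 2.34 ± 0.0647), TFC3, which encodes a TFIIIC subunit (I:151155-151531, 2.26 ± 0.00521), NOP9 (X:416683-417079, 2.59 ± 0.0966) and SEC9 (VII:508621-508956, 2.21 ± 0.270). The 25 regions broken in INO80 and not WT cells with HU lay mostly in Ty frames (18 regions), such as YJR029W and YMR045C, and 5 lay at Orc5 sites (position permutation, adjusted p = 1). These are stretches of frames and not newly broken frames, since 39 of the 40 Ty frames had a peak in at least 1 WT library with HU. Without HU, 30 regions were found in WT and not in INO80 cells, 13 of them at Orc5 sites (43.3%, position permutation, adjusted p = 0.0976), including FDH1, URA3 (V:116033-116910) and YAL063C-A. Of the 19 found in INO80 and not WT cells, 16 lay in Ty frames. Here too 39 of the 40 frames had a peak in at least 1 WT library. The HU and INO80 comparisons share the WT libraries with HU, and the Orc5 share was 50% of 6 regions (position permutation p = 0.258) with the higher-scoring peaks only.

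**Figure D2:**
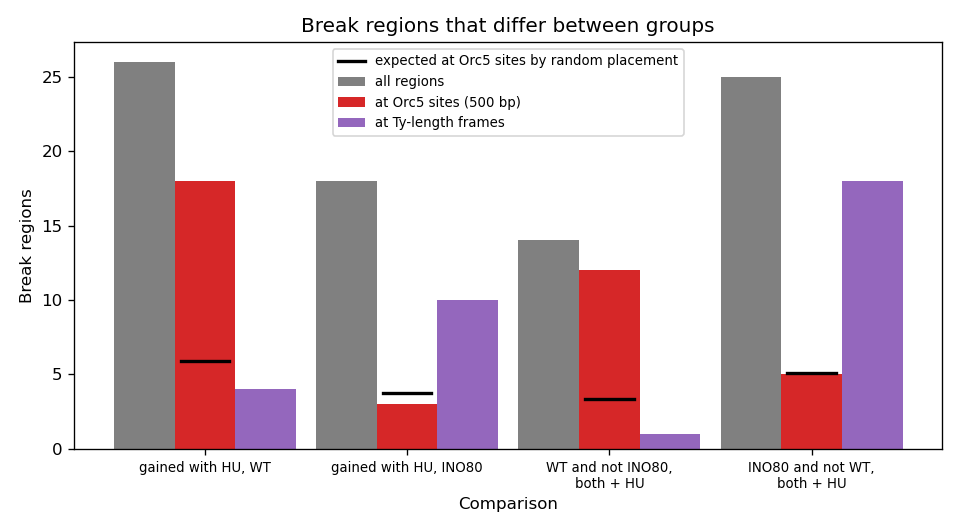
Number of break regions that differ between groups of 2 libraries (grey), of those at Orc5 sites (red) and of those at Ty-length frames (purple); the black line is the number at Orc5 sites expected by random placement. Regions gained with HU in WT (18 of 26 at Orc5 sites) and regions in WT and not INO80 cells with HU (12 of 14) lie above the line.

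The share of break peaks at Orc5 sites was lower with INO80 depleted. The mean fell from 32.7% ± 16.6 (SD, n = 8) in strains with INO80 to 11.1% ± 2.34 (n = 8) without it, a difference of -21.5 percentage points (exact two-sided permutation within Mot1 status and HU, p = 0.00154, the smallest the design allows; adjusted p = 0.0123 over 24 tests; lower in 4 of 4 strata). Much of that difference came from the short Mot1 lists, which stood in the group with INO80. Without lists of fewer than 50 peaks it was -6.93 percentage points, the strata left reach no exact p below 0.0556, and that is the p they gave. Against WT alone the differences were -7.18 points without HU and -6.68 with HU, where 2 libraries against 2 cannot go below an exact p of 0.333, and both gave that value. Leaving out 1 library moved them to between -11.5 and -2.90 points and between -12.4 and -0.985. The overall effect missed the threshold without ribosomal DNA, mitochondrial DNA and chromosome ends (-8.27 points, exact permutation p = 0.0756).

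Other classes moved with INO80 status as well. The Ty share was 49.3% ± 4.26 (SD, n = 8) with INO80 depleted and 27.8% ± 13.4 with it, 21.6 points higher (exact permutation p = 0.00617, adjusted p = 0.0247, 4 of 4 strata). Mitochondrial peaks were 4.88 points more frequent (exact permutation p = 0.00463, adjusted p = 0.0222), and the promoter share fell by 11.6 points, from 19.9% ± 7.48 to 8.27% ± 1.85 (exact permutation p = 0.00309, adjusted p = 0.0185). The Mot1 lists, with 0 mitochondrial peaks, enter these means too. Without lists of fewer than 50 peaks none of the 3 passed: the Ty difference was 7.88 points (exact permutation p = 0.222), the mitochondrial one 4.12 (p = 0.167) and the promoter one -8.55 (p = 0.111). Against WT alone the Ty share differed by 11.3 points without and 4.46 with HU (both exact permutation p = 0.667). Outside repeats the promoter difference was 6.77 points with all lists (exact permutation p = 0.483), where the Mot1 lists keep 12, 3, 7 and 0 peaks, and -16.3 without the short lists (exact permutation p = 0.167). The number of peaks was 1.90 log2 units higher with INO80 depleted (exact permutation p = 0.0448, adjusted p = 0.115), but -0.14 without the lists of fewer than 50 peaks. With the replicate block the unadjusted call was lost as well.

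The third comparison addressed depletion of Mot1. Its lists were the shortest. Without HU, of 40 and 14 peaks 16 and 4 lay at chromosome ends, 16 and 8 at Orc5 sites, 8 and 3 in Ty frames and 4 and 4 at ribosomal DNA, and classes overlap. Both Mot1 libraries and neither WT library had a peak in one stretch of RDN37-1 (XII:457544-459572, fold over background 6.05 ± 0.992, SD, n = 2), beside RDN37-2 (XII:459958-460617, 4.48 ± 0.751), at a subtelomeric frame on chromosome XII (5394-5767, 10.7 ± 2.07) and within FLO11, which encodes a flocculin (IX:391949-392330, 6.20 ± 0.0544). Of these 7 gained regions 5 were at Orc5 sites, against 0.998 expected (position permutation, adjusted p = 0.0270), all of them at ribosomal DNA (2) or within 12 kb of a chromosome end (3), and 201 regions of WT had no counterpart, among them another stretch of RDN37-1 (XII:451486-453356, 1.68 ± 0.209 in WT). With HU the Mot1 lists gained 2 regions and lacked 159. The strain depleted of both proteins gained 14 regions against WT, 11 of them in Ty frames, and lacked 29. With HU it gained 3 and lacked 41, of which 19 of the 39 nuclear ones were at Orc5 sites (position permutation, adjusted p = 0.0120). That set again rests on the WT libraries with HU, and its Orc5 share was not rerun with higher-scoring peaks or outside repeats.

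Across strains the number of peaks differed by -2.52 log2 units between lists with and without Mot1 depletion (exact permutation p = 0.00154, adjusted p = 0.0123, lower in 4 of 4 strata). Without lists of fewer than 50 peaks the difference was -0.48 (exact permutation p = 0.0556, the smallest those strata allow). The share of peaks at Orc5 sites was 28.7% ± 20.1 (SD, n = 8) with Mot1 depleted and 15.1% ± 5.70 with it, a difference of 13.7 points that did not pass the adjusted threshold (exact permutation p = 0.0386, adjusted p = 0.115). It turned to -0.953 points without the short lists and to -3.12 without ribosomal DNA, mitochondrial DNA and chromosome ends. Against WT alone, the Mot1 strain differed by 31.7 points and the strain depleted of both by -5.11 (exact permutation p = 0.333 and 0.667); with HU the differences were 24.8 and -10.7 points (both exact permutation p = 0.333). None of these tests of 2 libraries against 2 could have reached the threshold.

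ChIP-seq of Orc5 asked where Orc5 peaks remained when the tagged subunit was pulled from the nucleus. No untagged library is among the samples, so a peak that remained or was new need not mark the origin recognition complex. The list held 1415 peaks without and 1968 with rapamycin, from 1 library each, so no difference has a replicate check. Wide peaks became rarer: 243 peaks (17.2%) spanned at least 1 kb without and 171 (8.69%) with rapamycin. Of 1412 sites without rapamycin, 77.1% (exact binomial 95% interval 74.8 to 79.3) had a peak within 500 bp with rapamycin, and 72.8% overlapped one. Of sites at least 1 kb wide, 38.3% (32.2 to 44.8) were still covered over at least 50% of their length, against 63.2% (60.4 to 66.0) of narrower ones. By overlap the order was the opposite, with 85.4% (80.3 to 89.6) of wide and 70.2% (67.5 to 72.8) of narrower sites overlapping a peak. A wide site is harder to cover and easier to touch, and no expected share by width was computed. Both orders may therefore follow from width alone. At TRP1, next to the origin ARS1, coverage dropped from 2803 bp (IV:461379-464181) to 506 bp, and at the histone gene HHF1 from 1674 to 522 bp. Lost sites included those at HES1 (XV:781615-784367), at DIP5 and KEL3 (XVI:42467-44655) and at PPX1 (VIII:501000-503187). These intervals cover counting error only.

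Sites at tRNA genes mostly stayed. They made up 226 of the Orc5 sites against 38.2 expected by random placement (position permutation, adjusted p = 0.00476), and 97.3% (exact binomial 95% interval 94.3 to 99.0) overlapped a peak with rapamycin, against 68.1% (65.4 to 70.8) of sites elsewhere. At least 50% of their length stayed covered in 85.0% and 54.0%. All 24 sites at snoRNA and snRNA genes overlapped one. Promoters held 937 sites, 532 expected (position permutation, adjusted p = 0.00476). With rapamycin 861 sites were new by direct overlap, 538 of them at promoters, including sites at RPL2B and HIS5. Of the 861, 88 lay within 500 bp of a site without rapamycin, the one at HIS5 among them.

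Arp5 peaks were compared on the 11 chromosomes listed in all 4 libraries, with peaks of up to 10 kb. With rapamycin the tagged Arp5 itself was to be pulled from the nucleus. No untagged library is among the samples, so a listed peak need not mark Arp5. Peaks lay at promoters of 76.5% ± 0.718 (SD, n = 2) of 3741 protein-coding genes without rapamycin and 83.6% ± 1.40 with it. No expected share was computed, and the lists cover much of some chromosomes. In the first library without rapamycin called peaks covered 95.3% of chromosome I, 96.7% of III and 99.2% of VI, but 27.3% of XV. A peak at a promoter can therefore follow from coverage alone. Without rapamycin the share was 100% of the 7 phosphate and inositol genes, among them PHO5, which encodes an acid phosphatase, 92.9% ± 10.1 of the 7 histone genes, 65.6% ± 6.43 of the 77 ribosomal protein genes and 35.9% ± 2.21 of the 32 subtelomeric genes. The 10 kb limit removes peaks of 929 and 844 kb in all without and 370 and 899 kb with rapamycin, and genes inside them count as lacking a peak. With peaks of every width the shares were 87.8% ± 1.44 of all genes without and 91.2% ± 2.84 with rapamycin, and without it 70.3% ± 2.21 of the subtelomeric and 72.1% ± 6.43 of the ribosomal protein genes (SD, n = 2). The lists held 5321 ± 96.2 such peaks without and 5474 ± 421 with rapamycin (SD, n = 2 each; exact permutation p = 1). The libraries shared more with rapamycin absent (Jaccard index 0.735) than with rapamycin (0.529), a difference that was not tested. Between the conditions the index was 0.578, 0.592, 0.541 and 0.533, each above that of the libraries with rapamycin.

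Arp5 peaks were slightly more frequent near Orc5 sites than chance placement gave. This held in the lists with rapamycin too, where Arp5 was to be removed, so the excess need not reflect bound Arp5. Arp5 peaks lay within 500 bp of an Orc5 site 1.12 and 1.11 times as often as random positions without rapamycin (position permutation, adjusted p = 0.00722 each) and 1.08 and 1.10 times with it (adjusted p = 0.0192 and 0.00722, over 112 tests), so all 4 lists passed. Arp5 peaks also lay at promoters 1.22 and 1.18 times as often as random positions without and 1.15 and 1.27 times with rapamycin. Of the Orc5 sites 66.4% lay at promoters against 37.7% expected. Placement did not hold promoter position fixed, so the excess near Orc5 sites cannot be told apart from that at promoters. Direct overlap was less uniform. Orc5 sites overlapped an Arp5 peak 1.03 and 0.961 times as often as random positions without rapamycin (position permutation p = 0.112 and 0.0619), and 1.06 and 1.16 times with it (p = 0.002 each, the smallest the placements can give). Of all Arp5 peaks 21.8% ± 0.0575 (SD, n = 2) lay at Orc5 sites without and 22.1% ± 0.262 with rapamycin, and 81.4% ± 1.16 and 88.4% ± 7.72 of the 916 Orc5 sites had an Arp5 peak within 500 bp. By library these were 80.6% and 82.2% without and 93.9% and 83.0% with rapamycin, so the higher mean comes from 1 library, the one that lost least to the 10 kb limit; median peak widths were 269 and 318 bp. These shares gave exact permutation p = 0.333, the smallest 2 libraries against 2 allow, so the design could not show a difference. With the midpoint of the Orc5 site as the criterion, the excess of direct overlap in the first library with rapamycin ended (position permutation p = 0.855), and the second without rapamycin had fewer overlaps than chance (log2 of observed over expected -0.26, position permutation p = 0.002).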

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

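In this part, only the thinning test for read depth was chosen before its result was seen; the other tests were chosen after. A pair of contrasts is given here where every library moved one way in one background and the opposite way in the other. Of 78 pairs checked, 6 did so, and chance alone gives 4.33 without an effect. The opposite direction itself was not tested. Single differences against WT and between HU states were tested as 2 libraries against 2, where no exact permutation p below 0.333 is possible. Of the 6 pairs, 5 involve Mot1 lists of 40 peaks or fewer. No group has the 4 samples needed to look for single outlying libraries.

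Without HU, the number of peaks with INO80 depleted differed by -0.36 log2 units from WT and, with Mot1 depleted as well, by 3.71 from the Mot1 strain. Without HU, the Ty share with Mot1 depleted differed by -14.7 points against WT and by 3.80 points in the INO80 strain, and with HU by -26.6 and 9.65 points. With HU, the Orc5 share with Mot1 depleted differed by 24.8 points against WT and by -3.98 points in the INO80 strain, and the promoter share by 9.23 and -3.04 points. The promoter share with HU differed by 2.80 points in the INO80 strain and by -2.75 points in the strain depleted of both.

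Outside the chromosomes compared, the second Arp5 library with rapamycin listed 257 peaks on chromosome V and 831 on chromosome XVI, where the other 3 lists had none.

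The first pattern weighed is the shortness of the Mot1 lists. Mot1 depletion whatever the INO80 status is argued against as the whole cause, since lists depleted of both proteins held 0.736 times as many peaks as INO80 lists (0.908 without and 0.570 with HU), while a smaller effect and one that needs INO80 stay open. For lower read depth, the WT and INO80 lists were thinned to the Mot1 background, and 0 of 8 kept 5 to 40 peaks while 0 kept over 80, so the result met neither outcome set beforehand. The thinned lists kept at most 1 peak, their highest pileups (3 to 42) lay below those of the Mot1 lists (163 to 304) in 16 of 16 pairs, and Mot1 median folds were higher (5.14 to 6.05 against 1.87 to 2.74), but the Mot1 background rests on 1 peak per list and the highest pileup of 10 of the 12 other lists sits within 1 read of a limit of 2 per base of the smallest width, so thinned pileups may be too low and depth may still account for the pattern. A library that differs in more than depth also stays open, with 53.0% of Mot1 peaks overlapping another list.

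The second pattern is the concentration of break peaks at Ty frames, chromosome ends and other repeats. Depletion of INO80, alone or together with Mot1, is argued against as its source. Without HU, 181 repeat regions had a peak in both INO80 libraries or in both libraries depleted of both proteins. Of these, 72.4% were also broken in both WT libraries. The Mot1 strain did not enter this test, so it says nothing on depletion of Mot1 alone. More copies in the cells than in the reference could give such peaks in every strain, and repeat regions recurred in at least 9 of 12 lists 9.43 times as often as other regions (42.3% against 4.49%). Breaks that form at repeats in every strain would recur in the same way, so this value does not separate the explanations. Reads shared between near-identical genes stay open, since 26.7% of 15 such genes away from repeats had a break peak, namely ENA1, ENA5, HXT6 and HXT7.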

How the results depend on the processing

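The sets of Orc5 sites by width or loss, the filters on Ty frames and chromosomes, the number of peaks without short lists, the settings outside repeats, those for the Ty, promoter and mitochondrial shares and the Orc5 share of regions were chosen after seeing the data; the other alternatives were planned, and the cause of a change was not tested unless said. Calls here use the unadjusted p and 0.05. Annotated origins could not be run as planned, and the planned Orc5 alternative became the main definition.

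The HU effect on the Orc5 share (0.301 points) reversed without ribosomal DNA, mitochondrial DNA and ends (-1.05), with peak midpoints (-1.19), with base pairs (-0.622) and with Orc5 peaks of every width (-0.904), and was 6.83 without Ty frames too (p = 0.102, exact permutation) and 3.62 at Orc5 peaks of at least 1 kb (p = 0.0849); leaving out 1 library gave -1.84 (without the first Mot1 library) to 2.44. It also turned without the second WT (-0.771), first WT HU (-1.12), second INO80 (-0.0807), first Mot1 HU (-0.949) or first library depleted of both (-0.303). The INO80 effect (-21.5) kept its direction in all 13 alternatives. It lost its call without ribosomal DNA, mitochondrial DNA and ends (-8.27), without Ty frames too (-6.13), at Orc5 sites lost with rapamycin (-0.0602) and without lists of fewer than 50 peaks (-6.93, where no lower p was possible). It kept its call without any 1 library (-23.7 to -19.4). The Mot1 effect (13.7) lost its call with 2 kb windows (8.39), top scores (18.2), midpoints (9.79), base pairs (8.03) and log2 of observed over expected (0.56). It reversed without ribosomal DNA, mitochondrial DNA and ends (-3.12), without Ty frames too (-10.1), at Orc5 sites lost with rapamycin (-1.71) and without short lists (-0.953). Leaving out 1 library gave 11.5 to 15.8, and the call was lost without the second WT (12.6), second WT HU (12.2), first Mot1 HU (12.4) or second library depleted of both (13.0).

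Replicate 1 had the higher Orc5 share in 4 of 8 groups, but more peaks in 7 and as many in the eighth, so for the number of peaks a tie between libraries of 1 number is not excluded; the labels state none. With the replicate block the HU, INO80 and Mot1 effects had exact permutation p of 0.906, 0.00781 and 0.0781 (13.7 points), and for the number of peaks HU passed (-0.52, p = 0.0234) and INO80 did not (1.90, p = 0.102).

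For the number of peaks, HU passed with covered base pairs (-0.55) and without the first Mot1 HU library (-0.80, exact permutation p = 0.0216; range -0.80 to -0.24). INO80 ranged from 1.62 to 2.19, lost its call without either HU library depleted of both (1.87 and 1.94) and reversed without short lists (-0.14). Mot1 ranged from -2.81 to -2.24 and was -0.48 without short lists.

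For the Orc5 share, single strains against WT ranged over left-out libraries from -11.5 to -2.90 points (INO80), 23.1 to 40.3 (Mot1) and -9.40 to -0.826 (both), and with HU from -12.4 to -0.985, 19.1 to 30.5 and -16.3 to -4.96.

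The INO80 effects on the Ty (21.6), mitochondrial (4.88) and promoter (-11.6) shares lost their calls without short lists (7.88, 4.12 and -8.55, where no p below 0.0556 was possible) and kept them with the replicate block and without any 1 library (19.0 to 24.2, 4.01 to 5.75 and -13.9 to -9.25). Outside repeats the promoter effect turned to 6.77, and was -16.3 without short lists too, with no call in either.

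Enrichment at Ty frames, ends and subtelomeric families kept similar list counts. Depletion at promoters and between divergent genes kept them under the circular shift, top scores and midpoints, but went from 11 lists to 0 outside repeats, where few peaks remain. Lists depleted at Orc5 sites went from 8 to 3 (circular shift), 2 (top scores) and 0 (outside repeats) and enriched ones from 2 to 0, 0 and 5. Ribosomal DNA went from 6 lists to 1 (shift), 2 (top scores) and 2 (midpoints), and the 1 list enriched between divergent genes to 0 (top scores).

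Of 40 values (20 region counts under 2 alternatives) 18 moved by over 1.5 times. With 1 kb bins, gained regions of WT HU against WT were 40, and lost ones 26 (INO80 HU), 257 (Mot1 HU) and 66 (both, HU) against WT HU and 10 in INO80 HU against INO80. With top scores, which leave fewer peaks, gained counts were 9 (INO80), 4 (Mot1), 1 (Mot1 HU), 7 (WT HU), 9 (INO80 HU against INO80) and 1 (both, HU against none). Lost counts were 111 (Mot1), 6 (INO80 HU), 88 (Mot1 HU), 16 (both, HU), 27 (WT HU), 0 (Mot1 HU against Mot1) and 26 (both, HU against none). The Orc5 shares fell to 42.9% and 50%, and outside repeats were 81.8% and 84.6% with the calls kept.

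Orc5 retention was 72.8% for overlap, 88.8% within 2 kb, 66.0% for the wider peaks of each list and 70.3% for lists of equal length. With peaks of every width, chosen after seeing the data, promoters with an Arp5 peak went from 76.5% to 87.8% without and 83.6% to 91.2% with rapamycin for all genes, from 65.6% to 72.1% and 72.1% to 75.3% for ribosomal protein genes, and from 35.9% to 70.3% and 53.1% to 79.7% for subtelomeric genes, since genes in the wide peaks then count. The Arp5 share at Orc5 sites turned to -0.418 without chromosomes I, III and VI (left-out range 0.0901 to 0.461) and the share of sites to 0 with top scores (1.58 to 12.5). With Orc5 midpoints, log2 of observed over expected was -0.025 and -0.26 without rapamycin and 0.0097 in the first library with it; without I, III and VI it was -0.073 in the second without. That second library thereby passed for fewer overlaps than chance in both settings (position permutation p = 0.002 and 0.0340), a call opposite to the excess with rapamycin. No alternative was run for the placement test of Arp5 peaks within 500 bp of Orc5 sites.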

Other observations

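The tests of depth against break measures were chosen only after the results were seen. Over the 12 break lists other than Mot1, the lowest background went with the number of peaks (Pearson r = 0.619, permutation p = 0.0401, adjusted p = 0.0802 over 4 relations; Spearman rho = 0.295, permutation p = 0.351) and with the promoter share (r = 0.744, permutation p = 0.0138, adjusted p = 0.0550; rho = 0.594, permutation p = 0.0453, adjusted p = 0.181). For the Ty share r was -0.560 (permutation p = 0.0643, adjusted p = 0.0857) and for the Orc5 share 0.382 (permutation p = 0.202, adjusted p = 0.202). Without the 2 lists farthest from the median background, r for the first 2 was 0.0124 and 0.264, and for the Ty and Orc5 shares 0.122 and 0.140, so the relations rest on those lists.

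Break peaks recurred at some Orc5 sites in every list other than Mot1. The sites with a peak in the most libraries lay at chromosome ends, XII:5629-6029 in 15 and VIII:41-461 in 13 of the 16 libraries. The site at RFA1, which encodes the large subunit of replication protein A, and SEN34 (I:158372-160394) had a break peak within 500 bp in 12 lists. So did a site near YHR054C (VIII:214062-214407), beside the tandemly repeated CUP1 locus, one next to RDN37-1 (XII:449679-451275) and 2 at tRNA genes (XII:214924-214955 and XVI:560161-560349). Ty sequence outside the class of Ty-length frames was not looked for, so whether such sequence lies beside these sites is unknown. In all, 7.79% and 3.40% of the 1412 Orc5 sites had a break peak in the WT libraries and 2.90% and 1.77% in the INO80 libraries; with HU they were 5.17% and 3.33% in WT and 3.33% and 3.40% in the INO80 strain.

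Arp5 lists held long blocks past position 1 Mb on chromosomes VII and XV, such as VII:999742-1090990 in the first library without rapamycin. In 7 of 8 list and chromosome pairs the first block began within 1 kb of that position. The Orc5 lists had blocks there too, on VII and XII in both lists and on XV with rapamycin, starting at 1000001 on XII in both lists.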
